A study of Mus musculus with 12 samples.

How the data were processed

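The series holds 12 libraries of single LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction of blood progenitors that contains haematopoietic stem cells and multipotent progenitors. Per the labels, the cells were sorted by FACS from the liver of C57BL/6J mouse fetuses at embryonic day 18.5. The genotype label assigned 3 plates to wild type (WT), 3 to Rev1 knockout, 2 to homozygous Pcna K164R and 4 to the double mutant. Replicate numbers follow the order of deposit within a genotype and only name a plate. The labels give 3 sort dates, called sessions 1, 2 and 3 here. Session 1 holds WT replicate 1, both Pcna K164R plates and double mutant replicates 1 and 2. Session 2 holds Rev1 knockout replicate 1 and double mutant replicate 3. Session 3 holds WT replicates 2 and 3, Rev1 knockout replicates 2 and 3 and double mutant replicate 4. The sample titles name 5 flow cells, and no flow cell carried both WT and double mutant plates. Nothing in the labels says that the plates of a genotype come from separate animals, so every p-value measures the spread between plates, which may be partly technical.

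Per the labels' protocols, libraries were made with SORT-seq, a plate-based method that tags the 3' end of each mRNA with a cell barcode and a random molecular barcode (UMI), and were sequenced on a NextSeq 500. Per the submitters' processing notes, BWA 0.7.15 and the mouse build GRCm38 (mm10) were used, with no role stated for either. The counting tool and the gene annotation are not given in the sources used here. Each plate has 3 deposited tables over 384 wells, although the series text speaks of smaller plates: whole-number counts of observed UMIs, whole-number read counts, and transcript counts in which the authors corrected UMI counts for random barcodes drawn more than once. These transcript counts are expected counts that need not be whole, made by the authors from the observed UMI numbers by this correction before deposit. The correction was checked in the files. The deposited transcript counts followed the usual collision formula for 4096 random barcodes in every cell of all 12 plates within a tolerance of 0.011, and no UMI count exceeded its read count. The observed UMI counts were used for the main tests and the other deposited counts as alternatives.

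A well was kept with at least 1000 UMIs outside the ERCC spike-ins, the synthetic RNAs added to each well. This kept 3088 of 4608 wells, with 1520 below the minimum. Counts of the kept wells were summed per gene and plate, so that a plate and not a cell was the replicate. The summed depth ranged from 212938 UMIs in double mutant replicate 3 to 11617420 UMIs in double mutant replicate 1. Plates of a genotype were compared with a chi-square statistic over genes before they were averaged, and none were near-identical, with statistics per degree of freedom of at least 8.70. No doublet caller was run, the wells having been filled by a single-cell sort.

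Gene tests used edgeR 4.0.16 (R 4.3.3) with TMM scaling, its default filter on low counts, and the quasi-likelihood F-test in 1 fit over all 12 plates with genotype and sort session as terms. The filter left 12221 of 19463 genes. Adjusted p-values are from edgeR's test with Benjamini-Hochberg adjustment at a threshold of 0.05, log2 fold changes carry their standard error (SE), and CPM values are TMM-normalised unless stated otherwise. The 5 pairs of genotypes and the interaction of both mutations were tested. Lists of genes were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 35 lists of a comparison, then with an estimated correlation, and with fry (limma 3.58.1). DESeq2 1.42.0 was an alternative. Per-plate list scores are mean log2 CPM with a prior count of 2. Shares of cells and depths were compared with exact permutation tests of plates, two-sided on the absolute difference of means (scipy 1.17.1). The smallest p these can give is 0.0286 for 4 against 3 plates, 0.0667 for 4 against 2, and 0.1 for 3 against 3 or 3 against 2. Intervals of a share are exact Clopper-Pearson intervals at 95% and cover counting error only, and the limit given for a share of 0 is 3 cells of the total.

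The comparisons, the tests, the 21 gene lists, the 14 marker lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. By that rule the text draws on the 10 genes with the smallest p among those higher and among those lower past the threshold (all where fewer passed, and 3 per direction as values where fewer than 3 passed), Rev1 and Pcna throughout, and up to 4 members of each list by adjusted p. Genes chosen outside the rule are marked as such.

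For cell classes, each kept well was thinned to 1000 UMIs and clustered in scanpy 1.11.5 (2000 variable genes without cell-cycle genes, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster was named after a marker list only with at least 3 detected markers of which at least 2 stood among its 10 leading genes. These clustering settings were set after the plate sums had been tested. The 5 named classes were erythroid-like, macrophage-like, granulocyte-monocyte-like, B-lineage-like and mast cell-like. A cluster of shallow wells and the clusters without a name were kept apart. Marker genes define these clusters, so the shares of cells were also recomputed with marker and haem genes left out of the clustering.

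Positions are from the GRCm38 annotation and were found for 12141 of the 12221 tested genes. Genes within 20 Mb of a targeted gene were compared with all others by Fisher's exact test, with windows of 10 and 40 Mb as alternatives. The gene test was tested on simulated plates with 100 genes changed 2-fold and 100 changed 4-fold. For the double mutant against WT it recovered 34 and 81 of these, with 7 false calls in 122 over 11855 genes; for Rev1 knockout against WT 24 and 62, with 7 false calls in 93 over 11835 genes; for Pcna K164R against WT 7 and 52, with 6 false calls in 65 over 11841 genes. With the p53 list raised in a simulation of the double mutant against WT over 11859 genes, that list and 1 other were called, and with no list raised over 11852 genes none of the 35 was called. Neither simulation varied the correlation between genes, so calls that depend on the preset correlation were not tested.

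Alternatives covered scaling, DESeq2, the low-count filter, sort session and flow cell, single sessions, the Y-linked level as a covariate, the UMI minimum (500 and 2000), a mitochondrial share of at most 20%, thinning, read and transcript counts, mitochondrial genes, cell classes, and each plate left out in turn. Double mutant replicate 3 and Rev1 knockout replicate 1 are the only plates of session 2. Without either, the session term fits the other exactly, so these leave-outs are nearly the same fit in every comparison with sort session in the model. Results for some genes are not reported. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used for tables and figures.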

Results

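Transcript counts were analysed for LSK cells, the lineage-negative, Sca-1-positive, Kit-positive blood progenitors, from the liver of day 18.5 mouse fetuses. The 4 genotypes differ in 2 genes of DNA damage tolerance, the set of processes that let replication pass damaged template. Rev1 encodes a translesion DNA polymerase that also acts as a scaffold for others. Pcna encodes the sliding clamp of replicative polymerases, and the K164R change removes the lysine that is ubiquitinated when a fork meets damage. WT had 3 plates, Rev1 knockout 3, Pcna K164R 2 and the double mutant 4. The kept wells of WT replicates 1, 2 and 3 held 7259627, 2877113 and 2489661 UMIs. Those of Rev1 knockout replicates 1, 2 and 3 held 6170642, 4436835 and 4949562, and those of Pcna K164R replicates 1 and 2 held 8567277 and 4960419. Double mutant replicates 1, 2, 3 and 4 held 11617420, 9677881, 212938 and 2402867 UMIs. Double mutant replicate 3 was the thinnest plate, with 82 kept wells and a median of 1730 UMIs per well. The other plates had 107 to 381 kept wells and medians of 7537 to 34853 UMIs.

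Rev1 itself (chromosome 1, 38052786 to 38129921, GRCm38) was counted sparsely. WT plates held 80, 59 and 33 Rev1 UMIs, which is 11.0, 20.5 and 13.3 CPM before TMM scaling. Pcna K164R plates held 97 and 39 UMIs (11.3 and 7.86 CPM), and Rev1 knockout plates 37, 6 and 20 (6.00, 1.35 and 4.04 CPM). Double mutant replicates 1 and 2 held 15 and 24 UMIs (1.29 and 2.48 CPM) and replicate 3 held 1. The library labelled double mutant replicate 4 held 33 Rev1 UMIs, or 13.7 CPM, inside the WT range, and goes against its label. Any direction drawn with that library carries this doubt. The 3' tags counted here may lie outside the deleted part of Rev1, in which case they check nothing. The log2 fold change of Rev1 was -2.92 ± 0.66 (SE) in Rev1 knockout against WT (edgeR adjusted p = 0.301) and -1.39 ± 0.51 in the double mutant against WT (adjusted p = 0.129). Over leave-outs of single plates they ranged from -3.53 to -2.40 and from -2.40 to -0.39. In the double mutant against WT the value was -2.40 ± 0.55 without the library labelled double mutant replicate 4 (edgeR adjusted p = 0.133) and -0.39 without WT replicate 1. Neither passed the threshold after Benjamini-Hochberg adjustment, and DESeq2 called the former. Pcna (chromosome 2, 132249286 to 132253180) was abundant, at 601 ± 151 CPM in WT (SD, n = 3), 618 ± 163 in Rev1 knockout (n = 3), 800 ± 51.1 in Pcna K164R (n = 2) and 814 ± 316 in the double mutant (n = 4). A point change in the protein cannot be read from counts.

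The comparison of the double mutant with WT asks what the progenitors express when both routes are altered. Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases and is a p53 target, rose from 13.2 ± 7.49 CPM in WT (SD, n = 3) to 73.2 ± 16.6 in the double mutant (n = 4), a log2 fold change of 2.33 ± 0.26 (edgeR adjusted p = 0.00218). Flt3, the cytokine receptor of multipotent and lymphoid-primed progenitors, fell from 235 ± 25.0 to 49.7 ± 22.03 CPM. Hlf, a transcription factor of haematopoietic stem cells, fell from 401 ± 23.5 to 167 ± 42.5 CPM. The maternally expressed imprinted RNA Meg3 fell from 62.8 ± 4.57 to 9.32 ± 11.3 CPM, and the interferon-induced gene Ifi44 fell from 32.1 ± 10.1 to 1.61 ± 1.28 CPM. In all, 514 of 12221 genes passed, 220 higher and 294 lower in the double mutant. The balance turned in some alternatives: 328 were higher and 300 lower without mitochondrially encoded genes, 317 and 304 with a mitochondrial share of at most 20%, 63 and 59 with cells thinned to 1000 UMIs and 687 and 652 in session 3 alone. It was 1187 and 887 without Rev1 knockout replicate 1 and 1069 and 962 without double mutant replicate 3, which are nearly the same fit. Among alternatives chosen after seeing the data it was 319 and 304 without X and Y genes, 578 and 481 in Y-positive, Xist-negative wells and 25 and 77 without erythroid-like cells.

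**Figure D1:**
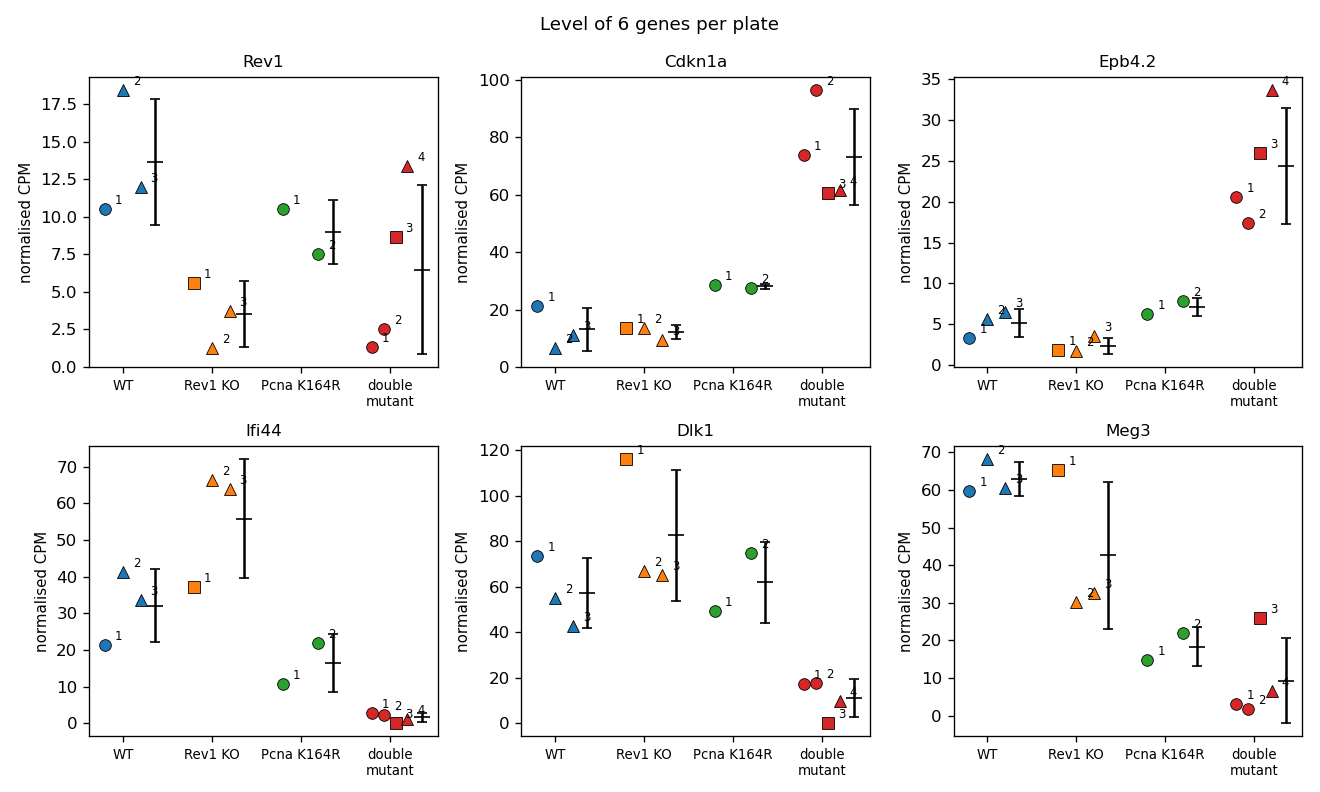
Normalised CPM of Rev1, Cdkn1a, Epb4.2, Ifi44, Dlk1 and Meg3 in each plate, grouped by genotype along the horizontal axis. Each point is a plate with its replicate number, circles, squares and triangles mark sort sessions 1, 2 and 3, and the black bars give the mean and SD; double mutant replicates 1, 2 and 4 lie above every WT plate for Cdkn1a, and the point of replicate 3 rests on 7 UMIs.

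For Cdkn1a, double mutant replicate 3 stood at 60.8 CPM after TMM scaling with a factor of 0.549 and at 32.9 CPM before it, near the Pcna K164R plates (28.8 and 31.0 CPM before scaling). The other genes with the smallest p among those higher were Ccrn4l (log2 fold change 1.56 ± 0.18), which encodes the rhythmic protein Nocturnin, Mrap (4.52 ± 0.55), an accessory protein of melanocortin receptors, Epb4.2 (2.50 ± 0.32), a protein of the red cell membrane skeleton, and the long non-coding RNA Pvt1 (2.41 ± 0.33). They also included Tango2 (1.55), Crip2 (2.996), the calcium-binding protein gene S100a6 (2.43), the RNA helicase gene Ddx39 (1.08) and Wdr55 (1.31), with edgeR adjusted p of 0.00287 to 0.0106. Among those lower, Wfdc17 had a log2 fold change of -3.73 ± 0.35, the chemokine gene Ccl4 -4.28 ± 0.45, the imprinted growth factor gene Igf2 -3.90 ± 0.42 and the imprinted Notch-family ligand gene Dlk1 -2.24 ± 0.26. Trim30d (-2.57) and Zfp608 (-1.70) were also lower.

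Target genes of p53, the transcription factor activated by DNA damage, were higher as a list, with a median log2 fold change of 0.76. Of 32 measured members 6 rose and none fell, and 13 rose and 2 fell when adjusted over the list alone. Besides Cdkn1a these included Ccng1 (1.04 ± 0.19), Bax (1.23 ± 0.22), a pore-forming protein of apoptosis, and the nuclease gene Aen (0.90 ± 0.19). Camera called the list (adjusted p = 1.07e-06), and the call was lost at an adjusted p = 0.0849 with an estimated correlation. By fry the adjusted p was 0.00799. The mean log2 CPM of the list was 4.67 to 4.75 in double mutant replicates 1, 2 and 4 and 4.05 to 4.22 in WT, but 3.65 in double mutant replicate 3, below every WT plate. The apoptosis list as a whole was not called (median -0.05, 1 of 23 higher and 1 lower, or 4 and 3 over the list alone). Among its members Bax rose and Bmf, a BH3-only protein gene, fell (-3.38). The same held for the senescence-associated list (median 0.07, 6 genes), where Cdkn1a alone rose, or 1 rose and 2 fell over the list alone.

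Interferon-stimulated genes, which encode antiviral and immune signalling proteins, were lower. Of 39 measured genes 18 fell and none rose, or 29 fell and 1 rose when adjusted over the list alone, with a median of -1.47. Ifit1 (-3.07 ± 0.42), Xaf1 (-1.90 ± 0.26) and Rsad2 (-3.33 ± 0.50) fell with Ifi44. Camera gave an adjusted p = 2.30e-24, and an adjusted p = 0.108 with an estimated correlation. The NF-kB and inflammatory list (median -0.56, 2 of 17 lower, camera adjusted p = 0.00232) had 3 members above 0, and the chemokine genes Ccl4 and Ccl3 (-3.96 ± 0.80) passed. MHC class I (median -0.52, none of 10 past the threshold, 2 lower over the list alone, adjusted p = 0.0320) and MHC class II genes (median -1.32, 1 of 8 lower, adjusted p = 0.0240) were lower as lists. With an estimated correlation these calls were lost, with adjusted p = 0.151, adjusted p = 0.335 and adjusted p = 0.465 in that order. Without the library labelled double mutant replicate 4 the NF-kB list (median -0.34) and both MHC lists (-0.34 and -0.86) were not called, nor MHC class I without WT replicate 2 (-0.39) or MHC class II without WT replicate 1 (-0.20).

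Genes of stem cells and of early lymphoid potential were lower in the double mutant. Of 24 stem cell (HSC) markers 7 fell and none rose, or 11 fell and 2 rose when adjusted over the list alone (median -0.80, camera adjusted p = 1.48e-08, adjusted p = 0.102 with an estimated correlation). Ly6a, which encodes the sorting antigen Sca-1, had a log2 fold change of -1.47 ± 0.26, and Txnip -1.06 ± 0.20. Among 16 lymphoid markers 5 fell and none rose, or 7 over the list alone (median -0.98, camera adjusted p = 1.61e-07, adjusted p = 0.151 with an estimated correlation), including the chromatin organiser Satb1 (-2.23 ± 0.36), Mef2c (-0.98 ± 0.19) and Notch1 (-1.37 ± 0.29). Fetal liver stem cell programme genes, among them several imprinted growth regulators, had 6 of 14 lower and none higher, or 8 lower and 2 higher over the list alone (median -0.999, adjusted p = 2.51e-06, adjusted p = 0.0658 with an estimated correlation). They included Igf2bp2 (-1.37 ± 0.19) and H19 (-2.16 ± 0.35) besides Igf2 and Dlk1. Dendritic markers (median -0.99, 2 of 10 lower, adjusted p = 0.00372) share Flt3 with the lymphoid list. Granulocyte-monocyte markers (median -0.62, 1 of 21 lower, adjusted p = 0.0283) had 2 members above 0, and Gfi1 (-1.59 ± 0.29) passed. For these 2 lists the values were adjusted p = 0.379 and adjusted p = 0.631 with an estimated correlation. Without the library labelled double mutant replicate 4 neither of the latter 2 lists was called, with medians of -0.46 and 0.20, and without WT replicate 3 the granulocyte-monocyte list was not called (-0.22). In session 1 alone the granulocyte-monocyte median was 0.40.

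Erythroid genes were higher. Haem synthesis and iron genes had 7 of 21 members higher and none lower, or 15 over the list alone (median 1.13, camera adjusted p = 1.53e-10, adjusted p = 0.151 with an estimated correlation). The transferrin receptor gene Tfrc stood at 1.73 ± 0.28, and the haem enzyme genes Fech at 1.42 ± 0.31 and Uros at 1.97 ± 0.43. Erythroid markers had 6 of 20 higher and none lower, or 15 higher and 1 lower over the list alone (median 1.31, adjusted p = 1.37e-08, adjusted p = 0.249 with an estimated correlation). They included the erythroid transcription factor gene Klf1 (2.29 ± 0.53), the blood group gene Rhd (2.26 ± 0.51) and Sphk1 (2.48 ± 0.59). Mature erythroid markers had 3 of 7 higher and none lower, or 4 over the list alone (median 2.22, adjusted p = 1.86e-06, adjusted p = 0.0787 with an estimated correlation), including the embryonic globin genes Hbb-y (7.26 ± 1.16, resting on 6 UMIs in the WT plates) and Hba-x (5.57 ± 0.91). The share of erythroid-like cells went with these lists, at 20.4%, 29.9% and 48.6% of kept wells in double mutant replicates 1, 2 and 4 and 5.78 ± 3.51% in WT (SD, n = 3), while double mutant replicate 3 could not be read for it. In unnamed clusters of ordinary depth alone, an alternative chosen after seeing the data, the erythroid median was 0.21 (camera adjusted p = 0.254), the haem median 0.28, the HSC median -0.27, the lymphoid median -0.80, the p53 target median 0.74 and the interferon median -1.30, the last 5 called by camera. That fit, here and in the other comparisons, also loses double mutant replicate 3, which had 1 such well. With that plate alone left out the medians were 1.28, 1.20, -0.71, -1.02, 0.81 and -1.36 in the same order. With erythroid-like cells alone left out, all 12 plates kept, they were 0.16, 0.28, -0.42, -0.62, 0.78 and -1.22, again an alternative chosen after seeing the data.

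**Figure D2:**
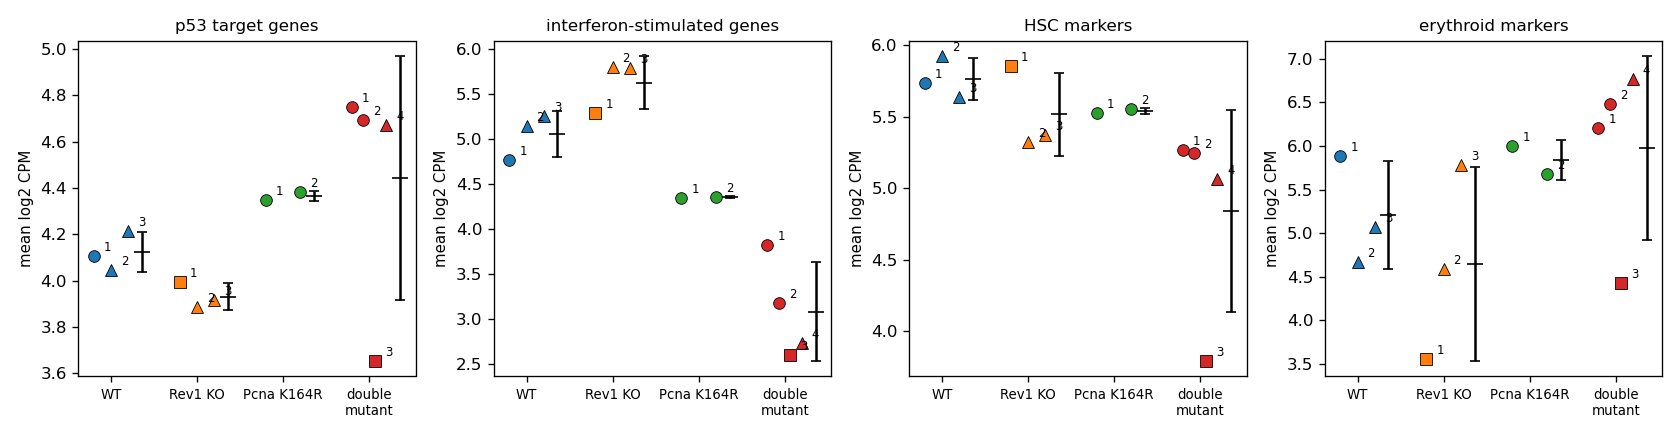
Mean log2 CPM of 4 gene lists (p53 target genes, interferon-stimulated genes, HSC markers and erythroid markers) in each plate, grouped by genotype; points, numbers and shapes stand for plates, replicates and sort sessions 1 (circle), 2 (square) and 3 (triangle), and black bars for the mean and SD. Double mutant replicate 3, the thinnest plate, lies lowest of its group for all 4 lists.

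Genes of the cell cycle and of energy metabolism moved less. G2/M genes had 5 of 55 higher and none lower, or 12 over the list alone (median 0.44, camera adjusted p = 3.32e-09, adjusted p = 0.151 with an estimated correlation), including the mitotic cyclin gene Ccnb1 (1.09 ± 0.24) and Gtse1 (1.09 ± 0.23), which is also on the p53 list. S-phase genes had 2 of 46 higher, or 3 over the list alone (median 0.36, adjusted p = 6.95e-05, adjusted p = 0.542 with an estimated correlation): Ccne1 (1.36 ± 0.26), the cyclin of S-phase entry, and the replication licensing gene Cdc6 (0.82 ± 0.20). Without the library labelled double mutant replicate 4 the S-phase list was not called (median 0.12). Oxidative phosphorylation genes had none of 72 past the threshold in edgeR and a median of 0.40 (adjusted p = 2.90e-07, adjusted p = 0.542 with an estimated correlation). Stress chaperone and unfolded-protein genes had 5 of 24 higher, or 6 higher and 1 lower over the list alone (median 0.30, adjusted p = 0.00372, adjusted p = 0.279 with an estimated correlation), among them the amino acid synthesis gene Asns (1.77 ± 0.37) and the mitochondrial chaperone genes Hspe1 (0.90 ± 0.19) and Hspd1 (0.99 ± 0.21).

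By fry 10 of the 35 lists passed: p53 target, interferon-stimulated, NF-kB, HSC and mature erythroid lists at an adjusted p = 0.00799 each, G2/M at 0.00864, the fetal liver list at 0.00192, lymphoid at 0.0153, and haem and MHC class I at 0.0390. Camera did not call the other 18 of the 35 lists. DNA repair genes were among them: the median was 0.02 for DNA damage tolerance genes, where 1 of 27 rose (Ube2v2, 0.71 ± 0.18), 0.19 for 19 Fanconi anaemia genes and 0.16 for 34 checkpoint and homologous recombination genes. It was -0.18 for immediate-early, 0.09 for glycolysis, 0.22 for mitochondrially encoded, -0.06 for ribosomal protein and -0.25 for histone genes. Among cell type markers it was 1.08 for B-lineage, -0.43 for T and innate lymphoid, 0.01 for megakaryocyte, 0.92 for mast cell and basophil, -0.35 for macrophage, -0.41 for neutrophil, -0.26 for hepatocyte and -0.66 for endothelial markers. Single members passed in some of these: Thy1 (2.09 ± 0.51) among T and innate lymphoid markers, Plek (-1.28 ± 0.29) among megakaryocyte markers, Klf6 (-1.45 ± 0.26) among immediate-early genes, and Slc16a3 (1.70) and Aldoc (-1.999) in glycolysis.

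The count of 514 genes rested on single plates and on which batch term was used. Without the library labelled double mutant replicate 4 it was 12, and without double mutant replicate 2, WT replicate 2, WT replicate 3, double mutant replicate 1, Rev1 knockout replicate 3 or Rev1 knockout replicate 2 it was 48, 81, 116, 219, 266 and 342. Without double mutant replicate 3 or Rev1 knockout replicate 1 it was 2031 and 2074. These are the only plates of session 2. Without either, the session term fits the other exactly, so the last counts are not separate evidence. Without the library labelled double mutant replicate 4, Ccrn4l (1.45), Crip2 (2.37), Ddx39 (0.99), Epb4.2 (2.54), Flt3 (-1.93), Hlf (-1.41), Mrap (3.79), Pvt1 (2.09), S100a6 (2.38), Tango2 (1.35) and Wdr55 (1.06) no longer passed. Cdkn1a passed in every leave-out (adjusted p = 0.0463 without that library in edgeR) but not with flow cell in place of sort session (3.15, adjusted p = 0.0652), in session 1 alone (1.99, adjusted p = 0.0731) or with read counts (2.61, adjusted p = 0.160). Session 1 alone gave 1 gene and session 3 alone 1339. Each of these fits had 5 plates and 2 residual degrees of freedom, with WT replicate 1 as the only WT plate of session 1 and the library labelled double mutant replicate 4 as the only double mutant plate of session 3. Flow cell in place of sort session gave none in edgeR (1376 at an unadjusted p under 0.05). No flow cell carried both genotypes, so that fit reached WT only through the other mutants, with 4 residual degrees of freedom. It took nothing from WT replicate 1 or double mutant replicates 3 and 4. DESeq2 called 1427 with sort session in the model.

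Rev1 knockout against WT asks what loss of the polymerase does alone. No gene passed in edgeR, with 1116 of 12221 at an unadjusted p under 0.05, and DESeq2 called 66. Genes with a small p that were higher included the septin gene Sept1 (log2 fold change 1.13 ± 0.21) and Znhit1 (1.26 ± 0.24). Among lower genes the smallest p belonged to the monocyte gene Ly6c2 (-4.64 ± 0.72), Gm4297 (1, 7 and 4 UMIs in the WT plates and 1, 0 and 0 in the knockout plates, too few for a fold change) and the AP-1 subunit gene Jun (-1.85 ± 0.35), each with an adjusted p = 0.232. These are values only.

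Of 35 lists camera called 8 in this comparison, and none of these with an estimated correlation. Higher were oxidative phosphorylation genes (median 0.37, adjusted p = 1.55e-10), ribosomal protein genes (0.44) and interferon-stimulated genes (0.63). So were mast cell and basophil markers (2.44) and B-lineage markers (1.70). With an estimated correlation the adjusted p was 0.155 for mast cell and basophil markers and 0.720 for each of the others. Lower were granulocyte-monocyte markers (-1.29, adjusted p = 0.639 with an estimated correlation), mature erythroid markers (-2.12, adjusted p = 0.639 with an estimated correlation) and HSC markers (-0.46, adjusted p = 0.720 with an estimated correlation). Adjusted over the list alone, 4 of 39 interferon-stimulated genes and 8 of 12 mast cell and basophil markers were higher, 9 of 21 granulocyte-monocyte markers were lower, and 1 of 7 mature erythroid markers was higher and 2 lower. No list passed by fry. Without the other named clusters the B-lineage median was -0.54. In unnamed clusters of ordinary depth the granulocyte-monocyte median was 0.31, and granulocyte-monocyte-like cells made up 0.525%, 2.62% and 5.85% of the WT plates. The WT plates carried Y-linked transcripts and the Rev1 knockout plates Xist, the X-inactivation RNA, so genotype and sex of the embryos go together in these 6 plates. The plates of the other genotypes allow a fit with the Y-linked level as a covariate, which takes the effect of sex as the same in all genotypes. It gave 0 genes in edgeR, with 1099 at an unadjusted p under 0.05 against 1116 without the covariate. In it camera called granulocyte-monocyte markers (-1.94), mast cell and basophil markers (2.27) and immediate-early genes (-0.73). It did not call the other 6 lists: oxidative phosphorylation (0.18), ribosomal protein (0.20), interferon-stimulated (0.30), B-lineage (2.30), mature erythroid (-1.41) and HSC (-0.41). The HSC call was lost without WT replicate 2 (-0.27), Rev1 knockout replicate 2 (-0.30) or replicate 3 (-0.32), the B-lineage call without WT replicate 3 (1.14) or Rev1 knockout replicate 2 (0.94), and the mature erythroid call without the latter (-2.13).

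Pcna K164R against WT asks the same of the clamp mutation. No gene passed in edgeR, with 239 at an unadjusted p under 0.05, and DESeq2 called 0. Genes with a small p that were higher included Il1rl1, the interleukin-33 receptor of mast cells (log2 fold change 2.11 ± 0.50), and the mast cell tryptase gene Tpsab1 (3.99 ± 1.00). Among lower genes the smallest p belonged to the mast cell protease gene Mcpt4 (-8.83 ± 1.44, with 1124 UMIs in WT replicate 1 and 0 in the other WT plates), Jmjd7 (-2.58 ± 0.62) and Meg3 (-1.42 ± 0.38). The adjusted p was 0.889 for Mcpt4 and 1 for the others.

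Camera called 13 lists here and none of them with an estimated correlation. Interferon-stimulated genes were lower (median -0.58, adjusted p = 1.35e-12, adjusted p = 0.324 with an estimated correlation). So were HSC markers (-0.36), MHC class II genes (-0.99), lymphoid markers (-0.26) and dendritic markers (-0.39). With an estimated correlation their adjusted p was 0.341, 0.324, 0.528 and 0.528 in that order. G2/M genes (0.34), mitochondrially encoded genes (0.37) and p53 target genes (0.10) were higher. So were haem synthesis and iron genes (0.30) and erythroid markers (0.43). Mast cell and basophil markers (1.94), neutrophil markers (1.73) and macrophage markers (0.16) were higher too. With an estimated correlation the adjusted p of the higher lists was 0.244, 0.324, 0.200, 0.528, 0.528, 0.114, 0.341 and 0.709 in that order. Adjusted over the list alone, 6 of 12 mast cell and basophil markers were higher, and no member of the other 12 lists passed. Mast cell-like cells made up 1.69% and 3.57% of the Pcna K164R plates and 0.525%, 0% and 0% of the WT plates (exact permutation p = 0.1, the smallest possible). That test takes no account of sort session: both Pcna K164R plates and the WT plate at 0.525% were sorted in session 1 and the WT plates at 0% in session 3. With sort session in the model edgeR gave a log2 difference of 2.82 (adjusted p = 0.367). In unnamed clusters of ordinary depth the erythroid median was -0.29, the haem median -0.02 and the macrophage median -1.41. The neutrophil median was -2.31 with flow cell in place of sort session and -2.92 without sort session. No list passed by fry. Single plates ended several of these calls: WT replicate 1 for p53 target genes (0.26 without it), MHC class II genes (-0.86), dendritic markers (-0.36) and neutrophil markers (-1.01). The library labelled double mutant replicate 4, through the shared session term, did so for the haem (-0.05), lymphoid (-0.05), erythroid (0.04), dendritic (-0.22) and macrophage (-0.16) lists. Pcna K164R replicate 1 did so for the haem (0.23), lymphoid (-0.37), erythroid (0.35), dendritic (-0.45) and macrophage (0.16) lists. WT replicate 2 did so for the haem (0.18), lymphoid (-0.23) and macrophage (-0.01) lists, and double mutant replicate 1 for the lymphoid (-0.25) and macrophage (0.14) lists. The macrophage call also ended without double mutant replicate 2 (0.05), double mutant replicate 3 (0.10), Rev1 knockout replicate 1 (0.10) or Rev1 knockout replicate 2 (0.17).

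The double mutant against Rev1 knockout asks what the clamp mutation adds where Rev1 is disrupted. Epb4.2 rose from 2.34 ± 1.02 CPM in Rev1 knockout (SD, n = 3) to 24.4 ± 7.12 in the double mutant (n = 4), a log2 fold change of 3.71 ± 0.39 (edgeR adjusted p = 0.00368). It lies on chromosome 2, within 20 Mb of Pcna. Cdkn1a rose from 12.3 ± 2.33 to 73.2 ± 16.6 CPM (2.17 ± 0.29, adjusted p = 0.0130), and Rgcc, a cell cycle regulator gene, rose from 18.3 ± 8.18 to 95.8 ± 54.8 CPM. Ifi44 fell from 55.9 ± 16.2 to 1.61 ± 1.28 CPM (-4.45 ± 0.47). In all 214 genes passed, 81 higher and 133 lower in the double mutant, and DESeq2 called 404 higher and 438 lower.

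Further genes higher were Ccrn4l (1.43), Crip2 (3.41), Daam1 (2.39), Darc (7.27, with 0, 0 and 1 UMIs in the knockout plates), Bcl2l15 (6.43, with 0, 1 and 0) and the transcription elongation factor gene Ell2 (1.55). Lower were Dlk1 (-2.78), the B cell transcription factor gene Pou2f2 (-2.73), Xaf1 (-2.70), Wfdc17 (-3.59), Ccl4 (-3.92), the antiviral enzyme gene Oas2 (-3.52), Cd4 (-3.07) and Meg3 (-2.74). Their edgeR adjusted p ranged from 0.00434 to 0.0227.

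Camera called 19 of 35 lists, 9 higher and 10 lower, and 1 of them, the mature erythroid markers, with an estimated correlation. That list had 3 of 7 members higher, or 7 over the list alone (median 4.24, camera adjusted p = 9.69e-12, adjusted p = 0.0315 with an estimated correlation). Interferon-stimulated genes had 20 of 39 lower, or 35 over the list alone (median -2.16, adjusted p = 2.80e-39, adjusted p = 0.121 with an estimated correlation). Lymphoid markers had 6 of 16 lower, or 9 over the list alone (-1.37, adjusted p = 0.171 with an estimated correlation), and p53 target genes 5 of 32 higher and 1 lower, or 15 and 2 over the list alone (0.76, adjusted p = 0.171 with an estimated correlation). Fetal liver stem cell programme genes had 5 of 14 lower and 1 higher, or 7 and 1 over the list alone (-0.69, adjusted p = 0.0974 with an estimated correlation). Haem synthesis and iron genes (0.94, 4 of 21 higher, 11 over the list alone, adjusted p = 0.244 with an estimated correlation) were higher. Erythroid markers (1.14, 1 of 20, 11 over the list alone, adjusted p = 0.259 with an estimated correlation) and G2/M genes (0.33, 2 of 55, 5 over the list alone, adjusted p = 0.244 with an estimated correlation) were higher. Mast cell and basophil markers were lower (-1.998, none of 12 past the threshold, 6 lower and 1 higher over the list alone, adjusted p = 0.221 with an estimated correlation). Of the other 10 lists called, those lower were dendritic markers (-0.97, adjusted p = 0.437 with an estimated correlation), MHC class I genes (-0.73, adjusted p = 0.293 with an estimated correlation) and NF-kB and inflammatory genes (-0.70, adjusted p = 0.259 with an estimated correlation). So were endothelial markers (-0.60, adjusted p = 0.259 with an estimated correlation), ribosomal protein genes (-0.56, adjusted p = 0.565 with an estimated correlation) and HSC markers (-0.31, adjusted p = 0.259 with an estimated correlation). Those higher were granulocyte-monocyte markers (0.67, adjusted p = 0.612 with an estimated correlation), mitochondrially encoded genes (0.61, adjusted p = 0.259 with an estimated correlation), stress chaperone and unfolded-protein genes (0.26, adjusted p = 0.293 with an estimated correlation) and S-phase genes (0.19, adjusted p = 0.674 with an estimated correlation). Each of these 10 but not the 9 before them lost its call in at least 1 leave-out. This happened without the library labelled double mutant replicate 4 for the S-phase (-0.08), NF-kB (-0.42), chaperone (0.16), MHC class I (-0.55), dendritic (-0.16) and endothelial (-0.74) lists. It happened without Rev1 knockout replicate 1 for the mitochondrially encoded (0.14), ribosomal (0.04), HSC (-0.04) and granulocyte-monocyte (0.82) lists. The values were 0.14, 0.04, -0.04 and 0.81 without double mutant replicate 3, which is nearly the same fit through the session term. The granulocyte-monocyte call was also lost without double mutant replicate 1 (0.35) or WT replicate 1 (0.15), and S-phase without Rev1 knockout replicate 2 (0.15) or 3 (0.08). MHC class I and dendritic markers lost it without Rev1 knockout replicate 3 (-0.71 and -0.57), and endothelial markers without double mutant replicate 1 (-0.57), double mutant replicate 2 (-0.48), WT replicate 1 (-0.50), Rev1 knockout replicate 2 (-0.77) or Rev1 knockout replicate 3 (-0.50). Some medians turned: in unnamed clusters of ordinary depth HSC markers had 0.32 and granulocyte-monocyte markers -0.77, the latter also -0.78 without the other named clusters and -0.12 in session 3 alone. With flow cell in place of sort session ribosomal protein genes had 0.19 and mast cell and basophil markers 0.61. By fry 8 lists passed: mature erythroid and fetal liver at an adjusted p = 0.00342, interferon-stimulated at 0.0352, p53 target, G2/M, lymphoid and mast cell and basophil at 0.0410, and NF-kB at 0.0422. Erythroid-like cells made up 0.612%, 2.35% and 9.05% of the Rev1 knockout plates.

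Single plates moved this count as well. Without the library labelled double mutant replicate 4 it was 2, without Rev1 knockout replicate 2 it was 7, without double mutant replicate 2 it was 28, without Rev1 knockout replicate 3 it was 62. Without WT replicate 2, WT replicate 3, Pcna K164R replicate 2 or Pcna K164R replicate 1 it was 100, 123, 128 and 130. Without WT replicate 1 it was 366, without double mutant replicate 3 it was 574 and without Rev1 knockout replicate 1 it was 590. Of the genes named, only Ifi44 passed without the library labelled double mutant replicate 4, where Cdkn1a stood at 1.81, Epb4.2 at 3.76, Rgcc at 2.17, Ccrn4l at 1.31, Crip2 at 2.41, Daam1 at 2.11, Darc at 6.14, Bcl2l15 at 5.86 and Ell2 at 1.11. There Dlk1 stood at -2.75, Pou2f2 at -2.65, Xaf1 at -2.30, Wfdc17 at -3.26, Ccl4 at -3.46, Oas2 at -2.81, Cd4 at -2.80 and Meg3 at -3.22. Without Rev1 knockout replicate 2, Cdkn1a (2.36), Rgcc (2.36), Ccrn4l (1.33), Crip2 (3.17), Daam1 (2.25), Darc (6.70), Bcl2l15 (8.54), Ell2 (1.44), Ccl4 (-3.86), Oas2 (-3.50), Cd4 (-2.68) and Meg3 (-2.70) did not pass. Bcl2l15 (6.40), Darc (7.26) and Ell2 (1.58) did not pass without double mutant replicate 2, nor did Bcl2l15 (5.83), Ccrn4l (1.47), Darc (9.07) and Ell2 (1.71) without Rev1 knockout replicate 3. With the Y-linked level as a covariate the count was 0 in edgeR (1354 at an unadjusted p under 0.05), in session 3 alone, where the library labelled double mutant replicate 4 is the only double mutant plate, 908, without a session term 433, and with flow cell in place of sort session 13.

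The double mutant against Pcna K164R asks what loss of Rev1 adds to the clamp mutation. The 5 genes that passed were all lower in the double mutant: Igf2 (log2 fold change -3.83 ± 0.45, edgeR adjusted p = 0.0230), Ifi44 (-2.81 ± 0.39), Wfdc17 (-2.51 ± 0.35), Meg3 (-2.60 ± 0.38) and Dlk1 (-1.87 ± 0.27), the latter 4 at an adjusted p = 0.0452. Igf2 went from 22.3 ± 8.15 CPM in Pcna K164R (SD, n = 2) to 1.23 ± 0.869 in the double mutant (n = 4). The smallest p among higher genes belonged to Cdkn1a (1.71 ± 0.28, adjusted p = 0.0650), Hba-x (6.96 ± 1.22) and Hbb-y (7.05 ± 1.24, both at an adjusted p = 0.0857), and these did not pass. At an unadjusted p under 0.05 there were 1175 genes, and DESeq2 called 40 higher and 51 lower.

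Camera called 17 lists in this comparison, none of them with an estimated correlation. Interferon-stimulated genes were lower (median -0.89, 1 of 39 past the threshold, 18 lower and 1 higher over the list alone, adjusted p = 0.274 with an estimated correlation). So were fetal liver stem cell programme genes (-0.61, 2 of 14, 8 lower and 2 higher over the list alone, adjusted p = 0.0650 with an estimated correlation) and lymphoid markers (-0.49, none of 16, 5 over the list alone, adjusted p = 0.274 with an estimated correlation). Higher were haem synthesis and iron genes (0.90, 5 of 21 over the list alone, adjusted p = 0.274 with an estimated correlation), mature erythroid markers (2.53, 3 of 7 over the list alone, adjusted p = 0.0832 with an estimated correlation) and p53 target genes (0.33, 2 of 32 over the list alone, adjusted p = 0.0650 with an estimated correlation). The other 11 lists called were oxidative phosphorylation genes (0.28, adjusted p = 0.558 with an estimated correlation), erythroid markers (0.93, adjusted p = 0.352 with an estimated correlation) and HSC markers (-0.41, adjusted p = 0.279 with an estimated correlation). They also held S-phase genes (0.19), G2/M genes (0.09) and NF-kB and inflammatory genes (-0.50). Stress chaperone and unfolded-protein genes (0.37), neutrophil markers (-2.57) and mast cell and basophil markers (-0.95) followed. From S-phase genes on, the adjusted p with an estimated correlation was 0.577, 0.577, 0.274, 0.274, 0.410 and 0.279 in that order. The last were immediate-early genes (-0.39, adjusted p = 0.279 with an estimated correlation) and MHC class I genes (-0.42, adjusted p = 0.293 with an estimated correlation). Without the other named clusters the mast cell and basophil median was 0.07. By fry the p53 target (adjusted p = 0.0296) and fetal liver (adjusted p = 0.0107) lists passed. Of these 11 lists, the G2/M call was lost without double mutant replicate 2 (0.04), Pcna K164R replicate 2 (0.09) or WT replicate 3 (0.09). The immediate-early call was lost without double mutant replicate 1 (-0.36) or Pcna K164R replicate 2 (-0.19), and the MHC class I call was lost without double mutant replicate 2 (-0.43), WT replicate 1 (-0.33), Pcna K164R replicate 1 (-0.55), Pcna K164R replicate 2 (-0.27) or the library labelled double mutant replicate 4 (-0.36). The count of 5 genes became 0 without double mutant replicate 1, double mutant replicate 2, Pcna K164R replicate 2 or WT replicate 3, 1 without WT replicate 2 or the library labelled double mutant replicate 4, 2 without WT replicate 1, 20 without Rev1 knockout replicate 1 and 24 without double mutant replicate 3. Igf2 did not pass without double mutant replicate 1 (-3.67), double mutant replicate 2 (-3.84), Pcna K164R replicate 2 (-3.39) or WT replicate 3 (-3.77), and Ifi44, Wfdc17, Meg3 and Dlk1 each did not pass in 8 or 9 leave-outs, where their values nearest 0 were -2.21, -2.02, -2.19 and -1.53.

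The interaction of both mutations asks whether their effects add on the log scale. The Rev1 knockout plates, all with Xist, enter this contrast, so sex of the embryos is not separated from it either. No gene passed in edgeR, with 640 at an unadjusted p under 0.05, and DESeq2 called 32. The genes with the smallest p were Epb4.2 (2.63 ± 0.49), Ly6c2 (5.35 ± 0.99) and Slc4a1, the red cell anion exchanger gene (5.45 ± 1.13), above 0, and Ifi44 (-3.75 ± 0.50, adjusted p = 0.0911), Dlk1 (-2.41 ± 0.37) and Tpsab1 (-8.58 ± 1.38, with 0 UMIs in WT replicates 2 and 3 and double mutant replicate 3) below 0. Of 15 lists called by camera, 2 kept the call with an estimated correlation, both at an adjusted p = 0.0101. Mature erythroid markers had a median of 5.05, with 7 of 7 above 0 and 5 past the threshold over the list alone. Their values rest partly on few UMIs. Hbb-y had 3, 1 and 2 in the WT plates, 7 and 1 in the Pcna K164R plates and 0 in double mutant replicate 3. The log2 interaction of the erythroid-like share was 1.24 (edgeR adjusted p = 0.412). Mast cell and basophil markers had a median of -3.53, with 9 of 12 below 0, all 9 past the threshold over the list alone. With an estimated correlation interferon-stimulated genes (-1.51, 37 of 39 below 0, 26 past the threshold over the list alone) lost the call at an adjusted p = 0.0639. So did p53 target genes (0.62, 28 of 32 above 0, 2 past the threshold over the list alone) at an adjusted p = 0.0545. By fry 4 lists passed: p53 target genes (adjusted p = 0.0447), the fetal liver list (adjusted p = 0.0279), and mature erythroid and mast cell and basophil markers (adjusted p = 0.0187 each).

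Among cell classes, erythroid-like cells, whose 10 highest genes included Klf1, Rhd, Rhag, Ermap and Cpox, were the most frequent of the named ones. They made up 73 of 357 wells (20.4%, 95% Clopper-Pearson interval 16.4 to 25.0), 80 of 268 (29.9%, 24.4 to 35.7) and 52 of 107 (48.6%, 38.8 to 58.5) in double mutant replicates 1, 2 and 4. Of the 82 kept wells of double mutant replicate 3, 81 fell in the shallow cluster, where no class can be read, so its share of 0% is no measurement. In WT they were 9.71%, 2.95% and 4.68%, and in Pcna K164R 12.1% and 8.57%. With that plate counted as 0% the difference between double mutant and WT did not pass (exact permutation p = 0.2), nor did those between the double mutant and Rev1 knockout (p = 0.171, exact permutation) or Pcna K164R (p = 0.467, exact permutation). With edgeR on cell numbers and sort session the log2 ratio of double mutant to WT was 2.34 (adjusted p = 0.0638). For the share of erythroid-like cells, double mutant against WT, the difference was 15.4 percentage points within session 1 (1 WT plate), 44.8 within session 3 (1 double mutant plate) and 27.2 without replicate 3 (exact permutation p = 0.1, the smallest possible). A Sca-1 and Kit gate lies before all these shares.

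**Figure D3:**
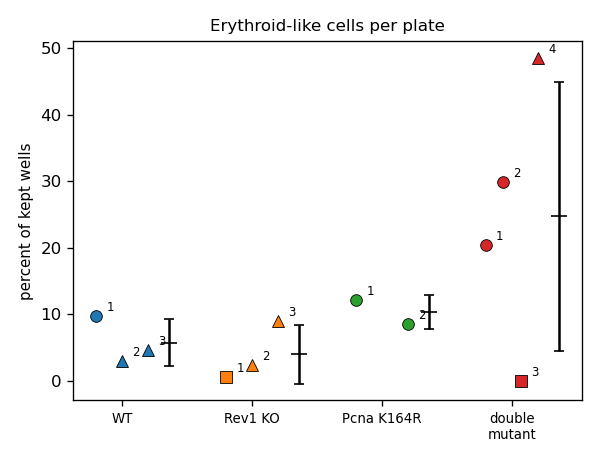
Percent of kept wells in the erythroid-like class in each plate, grouped by genotype; points are plates with replicate numbers, circles, squares and triangles mark sort sessions 1, 2 and 3, and black bars give the mean and SD. Double mutant replicates 1, 2 and 4 lie at 20.4%, 29.9% and 48.6%, against 2.95% to 9.71% in WT, and the 0% of replicate 3 comes from a plate whose wells could not be classed.

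Median UMIs per kept well were 22472 ± 14740 in the double mutant (SD, n = 4), 11592 ± 3759 in WT (n = 3), 17055 ± 695 in Rev1 knockout (n = 3) and 18355 ± 3969 in Pcna K164R (n = 2). With all plates the difference between double mutant and WT did not pass (exact permutation p = 0.286), nor did that in median genes per well (p = 0.714, exact permutation). Double mutant replicates 1, 2 and 4 had 30735, 34853 and 22571 UMIs and 5823, 6042 and 5346 genes, all above the highest WT plate (14960 and 4257), and replicate 3 had 1730 and 650. For median UMIs per kept well, double mutant against WT, leave-outs added after the data were seen moved the difference from 10880 to 17794 without double mutant replicate 3 (exact permutation p = 0.1, the smallest possible) and to 6753 without double mutant replicate 2. For median genes per kept well, double mutant against WT, it moved from 779 to 2050 without double mutant replicate 3 (exact permutation p = 0.1), 326 without double mutant replicate 1, 253 without double mutant replicate 2, 437 without WT replicate 2 and 485 without the library labelled double mutant replicate 4. Genes near the targeted loci were not called more often than others. In the double mutant against WT 17 of 357 genes within 20 Mb of Rev1 or Pcna passed against 496 of 11782 elsewhere (Fisher's exact p = 0.592). Against Rev1 knockout it was 5 of 241 within 20 Mb of Pcna and 208 of 11898 elsewhere (Fisher's exact p = 0.618).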

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

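The tests of erythroid-like cells, of the library labelled double mutant replicate 4 and of mixed embryos in this part were chosen after the results were seen, and those of sort session, the thinnest plate and the splits before. The test of sex was added after the data were seen, with its prediction written before its own result.

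The p53 target genes, higher in the double mutant than in WT, might reflect more erythroid-like cells, the sex of the embryos or the sparsely filled double mutant replicate 3. The first explanation predicts a median near 0 in unnamed clusters of ordinary depth, and it was 0.74. That fit also loses replicate 3, and with erythroid-like cells alone left out and all plates kept the median was 0.78. Sex predicts the same in Y-positive, Xist-negative wells. There camera called the list with a median of 0.69 over 7 plates, again without replicate 3. Replicate 3 had the lowest mean log2 CPM of the list among all plates (3.65), so it pulled against the rise, and the median of 0.81 without it adds no further evidence. Neither erythroid-like cells nor sex alone accounts for the pattern. Both together, cell mixture within the unnamed clusters and flow cell were not tested here, and the camera call rests on a preset correlation.

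The interferon-stimulated genes, lower in the double mutant, might reflect the same cell mixture, sex or the sort session. The median log2 fold change was -1.30 in unnamed clusters of ordinary depth, -1.22 with erythroid-like cells alone left out and -1.61 in Y-positive, Xist-negative wells. Within session 1 it was -1.15 and within session 3 it was -2.32, but the former rests on 1 WT plate and the latter on 1 double mutant plate, the library labelled replicate 4. The fit over all plates with sort session in the model gave -1.47. None of these explanations removes the difference, though single plates weigh little against sort session. Flow cell was not tested here, since no flow cell carried both genotypes. Animals within a session may still differ in exposure, which the data cannot show.

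The library labelled double mutant replicate 4 had Rev1 counts near the WT level, which might come from a mislabelled Pcna K164R or WT library. Either predicts a Cdkn1a level inside the range of that genotype. The library had 63.3 CPM of Cdkn1a before scaling, against 28.8 to 31.0 in Pcna K164R and 7.65 to 22.5 in WT. In unnamed clusters of ordinary depth it had 94.6 CPM, against 17.0 to 27.6 and 7.85 to 16.5. Both exchanges are argued against by a single gene, which was itself called with this library in its group.

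The 514 genes of the double mutant against WT were compared with every regrouping of the 7 plates into 4 and 3. Of 35 splits, 3 gave as many genes, the true one included, and the highest other gave 659, with double mutant replicate 3 exchanged to the side of the WT plates. Another, with double mutant replicates 1, 2 and 3 and WT replicate 1 on a side, gave 569 and follows the sort sessions, within which the true comparison, with 1 plate of a genotype in each, gave 1 and 1339. Both break the numbers of each genotype within the sessions. Among the 9 splits that keep them, a count added after the results were seen, only the true one gave any gene, and the highest other gave 0. Chance is not excluded as a source of the count, since 9 splits are few. In the double mutant against Rev1 knockout 1 of 35 splits gave as many as 214, and the highest other gave 61. Of the 6 that keep the sessions 1 gave as many, and the highest other gave 2. In Rev1 knockout against WT the true count is 0, so all 10 splits gave as many, the highest other gave 0, and the test says nothing.

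Of 50 groups of values searched for a plate far from the others of its genotype, 8 held such a plate, each time double mutant replicate 3. It had a median of 650 genes per kept well. Its median mitochondrial percent was 11.0. Its share of wells in the shallow cluster was 98.8%. Its mean log2 CPM was 3.65 for p53 target genes, 6.13 for G2/M genes, 5.89 for oxidative phosphorylation genes, 2.70 for fetal liver stem cell programme genes and 3.79 for HSC markers.

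For the interaction camera, which sets a list against the other genes, called 15 lists, and leaving out 1 plate ended 7 of these calls. By fry, which tests a list against no change, 4 lists passed. The median was 0.62 for p53 target genes (adjusted p = 1.16e-06, adjusted p = 0.0545 with an estimated correlation) and -1.51 for interferon-stimulated genes (adjusted p = 1.93e-36, adjusted p = 0.0639 with an estimated correlation). It was -0.52 for NF-kB and inflammatory genes and 0.23 for stress chaperone and unfolded-protein genes (adjusted p = 0.310 for both with an estimated correlation). It was 0.81 for haem synthesis and iron genes and -0.57 for MHC class I genes (adjusted p = 0.310 for both with an estimated correlation). It was -0.44 for ribosomal protein genes, -0.50 for fetal liver stem cell programme genes, 1.06 for granulocyte-monocyte markers and -1.07 for lymphoid markers. With an estimated correlation their adjusted p was 0.775, 0.0639, 0.443 and 0.134 in that order. The granulocyte-monocyte median turned to -0.43 in unnamed clusters of ordinary depth and to -0.05 without the other named clusters. The median was -0.45 for megakaryocyte markers, 0.82 for erythroid markers and -1.16 for macrophage markers. With an estimated correlation their adjusted p was 0.310, 0.451 and 0.719 in that order. Mature erythroid markers (5.05) and mast cell and basophil markers (-3.53) kept the call with an estimated correlation (adjusted p = 0.0101 for both). Only 26 wells over all plates were mast cell-like.

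Those 7 interaction lists, with their medians in the leave-outs that ended the call, were as follows. NF-kB and inflammatory genes had -0.25 without WT replicate 1, -0.42 without Pcna K164R replicate 2, -0.36 without the library labelled double mutant replicate 4 and -0.47 without Rev1 knockout replicate 2. Stress chaperone and unfolded-protein genes had 0.22 without Pcna K164R replicate 2, 0.24 without the library labelled double mutant replicate 4 and 0.25 without Rev1 knockout replicate 2. MHC class I genes had -0.61 without double mutant replicate 2, -0.50 without WT replicate 1, -0.41 without Pcna K164R replicate 2, -0.58 without WT replicate 3, -0.43 without the library labelled double mutant replicate 4, -0.67 without Rev1 knockout replicate 2 and -0.50 without Rev1 knockout replicate 3. Ribosomal protein genes had -0.23 without WT replicate 1, -0.25 without Pcna K164R replicate 2, -0.02 without Rev1 knockout replicate 1 and -0.01 without double mutant replicate 3. Erythroid markers had 0.03 without WT replicate 1 and 0.55 without Rev1 knockout replicate 2. Megakaryocyte markers had -0.40 without double mutant replicate 2, -0.48 without Pcna K164R replicate 1, -0.51 without WT replicate 2, -0.46 without WT replicate 3, -0.44 without the library labelled double mutant replicate 4, -0.33 without Rev1 knockout replicate 2 and -0.43 without Rev1 knockout replicate 3. Macrophage markers had -1.01 without double mutant replicate 1, -0.83 without double mutant replicate 2, -1.05 without Pcna K164R replicate 1, -0.71 without WT replicate 2, -1.18 without Rev1 knockout replicate 2 and -0.70 without Rev1 knockout replicate 3.

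UMIs per spiked ERCC UMI were not part of the planned comparisons, and averaged 50.7 ± 6.28 in the double mutant (SD, n = 4), 27.8 ± 2.32 in WT (n = 3), 28.2 ± 2.58 in Rev1 knockout (n = 3) and 39.7 ± 13.7 in Pcna K164R (n = 2). The exact permutation p was 0.0286 against WT and against Rev1 knockout, the smallest possible. Among plates of a single flow cell, double mutant replicate 2 had 58.8 and Rev1 knockout replicate 1 had 25.6, while double mutant replicate 1 had 49.1 and Pcna K164R replicate 1 had 49.4. In unnamed clusters of ordinary depth the means were 47.2 in the double mutant and 25.1 in WT (exact permutation p = 0.1, 3 plates each).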

How the results depend on the processing

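The alternatives named as added in this part were chosen after the results were seen: unnamed clusters of ordinary depth alone (which also loses double mutant replicate 3), erythroid-like cells left out, the double mutant without replicates 3 and 4, X and Y genes left out, Y-positive Xist-negative wells, clustering without marker and haem genes, the shallow cluster left out, UMIs per ERCC UMI, and depth with each plate left out. No paired analysis was possible because replicate numbers follow the order of deposition and the labels pair no plates. Of gene list results 2478 stayed the same, 387 weakened and 30 reversed. Of named genes 1689 stayed the same, 62 were stronger and 310 weaker. Of counts 90 stayed within 1.5 times and 99 moved. The cause of these moves was not tested.

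Counts are given for the double mutant against WT, Rev1 knockout against WT, Pcna K164R against WT, the double mutant against Rev1 knockout, the double mutant against Pcna K164R and the interaction, in that order. By edgeR they were 514, 0, 0, 214, 5 and 0, and by DESeq2 1427, 66, 0, 842, 91 and 32. Without a filter on low counts they were 1199, 323, 36, 1109, 217 and 242. With flow cell in place of sort session they were 0, 6, 5, 13, 0 and 9. Over leave-outs of single plates they ranged from 12 to 2074, 0 to 5, 0 to 1, 2 to 590, 0 to 24 and 0 to 7.

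In the double mutant against WT the count was 1 in session 1, 1339 in session 3, 122 with cells thinned to 1000 UMIs, 1 with read counts and, among the added alternatives, 1016 in unnamed clusters, 102 without erythroid-like cells, 72 without replicates 3 and 4 and 1059 in Y-positive Xist-negative wells. In Rev1 knockout against WT it was 16 in session 3, 3 thinned, 2 with wells of at least 2000 UMIs, 14 in unnamed clusters and 4 without double mutant replicates 3 and 4. In Pcna K164R against WT it was 2 in Y-positive Xist-negative wells. In the double mutant against Rev1 knockout it was 908 in session 3, 94 thinned, 0 with read counts, 433 without sort session, 0 with the Y-linked covariate, 89 without erythroid-like cells and 9 without replicates 3 and 4. In the double mutant against Pcna K164R it was 3 in session 1, 31 in unnamed clusters, 10 without the other named clusters, 3 without erythroid-like cells, 3 without replicates 3 and 4, 3 without mitochondrially encoded genes and 3 without X and Y genes. It was 1 with wells of at least 500 UMIs, with transcript counts and in Y-positive Xist-negative wells, and 0 thinned, with read counts, without sort session and with the Y-linked covariate. In the interaction it was 3 thinned, 6 with wells of at least 2000 UMIs, 18 in unnamed clusters, 1 without erythroid-like cells and 1 without double mutant replicates 3 and 4.

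Read counts in place of UMIs moved the median over all genes to -0.11, 0.11, -0.24 and -0.17 in the double mutant against WT, Rev1 knockout against WT, the double mutant against Rev1 knockout and the interaction. DESeq2 called 404 higher and 438 lower in the double mutant against Rev1 knockout, where edgeR called 81 and 133, and 40 and 51 against Pcna K164R, where edgeR called 0 and 5.

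Rev1 passed in Rev1 knockout against WT with DESeq2 (-2.95) and without the filter (-2.85), where it also passed in the double mutant against WT (-1.35) and against Pcna K164R (-1.73). The Pcna gene ranged from -0.0340 to 0.70 over leave-outs in the double mutant against WT.

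List medians that reversed were as follows. With flow cell in place of sort session, neutrophil markers were -2.31 in Pcna K164R against WT, ribosomal protein genes 0.19 and mast cell and basophil markers 0.61 in the double mutant against Rev1 knockout, and ribosomal protein genes 0.0661 in the interaction. In session 1, granulocyte-monocyte markers were 0.40 in the double mutant against WT, and erythroid markers -0.0582 and macrophage markers -0.31 in Pcna K164R against WT. In session 3 granulocyte-monocyte markers were -0.12 in the double mutant against Rev1 knockout. In unnamed clusters, granulocyte-monocyte markers were 0.31 in Rev1 knockout against WT, -0.77 in the double mutant against Rev1 knockout and -0.43 in the interaction, HSC markers 0.32 in the double mutant against Rev1 knockout, and haem synthesis and iron genes -0.0204, erythroid markers -0.29 and macrophage markers -1.41 in Pcna K164R against WT. Without erythroid-like cells haem synthesis and iron genes were -0.0631 in that comparison. Without double mutant replicates 3 and 4 erythroid markers were -0.0552 and macrophage markers -0.31 there, and ribosomal protein genes 0.13 in the double mutant against Rev1 knockout and 0.0173 in the interaction. Without sort session neutrophil markers were -2.92 in Pcna K164R against WT and mast cell and basophil markers -0.0514 in the double mutant against Rev1 knockout. Without the other named clusters B-lineage markers were -0.54 in Rev1 knockout against WT, granulocyte-monocyte markers -0.78 in the double mutant against Rev1 knockout and -0.0483 in the interaction, and mast cell and basophil markers 0.0662 in the double mutant against Pcna K164R. With the Y-linked covariate the interaction gave 0.0396 for chaperone and -0.10 for ribosomal protein genes, reversed in camera's direction and not in the sign of the median. Over leave-outs granulocyte-monocyte markers ranged from -1.72 to 0.20 in the double mutant against WT and S-phase genes from -0.0777 to 0.37 in the double mutant against Rev1 knockout.

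For the share of granulocyte-monocyte-like cells, double mutant against Rev1 knockout, the difference was -5.75 percentage points with the Leiden resolution doubled (exact permutation p = 0.0286), where 144 of the 180 wells so named form a cluster whose highest marker list is dendritic, with Irf8, Mpeg1 and H2-Aa. For UMIs per ERCC UMI the double mutant exceeded WT by 22.9 and Rev1 knockout by 22.5. For the share of erythroid-like cells, double mutant against WT, the difference was 27.2 points without double mutant replicate 3 and 27.8 without the shallow cluster (exact permutation p = 0.1 for both), and 19.3 when cells were clustered without marker and haem genes (p = 0.2, exact permutation).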

Other observations

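The tests of mixed embryos and of the segment beside Pcna in this part were chosen after the results were seen.

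Double mutant replicates 1 and 2 each held wells of both sexes. Replicate 1 had 145 wells with Xist and no Y-linked UMI, 108 with Y-linked UMIs and no Xist and 56 with both, and replicate 2 had 47, 137 and 52. Along the plate, neighbouring wells of the first 2 kinds changed from one to the other 23 times in 252 pairs in replicate 1 and 9 times in 183 in replicate 2, against at least 97 and 53 in 1000 random orders. The separate stretches in these 2 plates show cells of more than 1 embryo, since RNA carried between wells would likely mix the wells of these kinds. The wells with both were left out of this test, are more numerous than the 0 to 4 on each other plate, and their source, free RNA and doublets included, stays open. The library labelled double mutant replicate 4 had 81 Y-linked wells and 0 with Xist alone, and double mutant replicate 3 had 11 and 4. WT plates were mostly Y-linked, with 3 wells of Xist alone in WT replicate 3 and 2, 3 and 2 wells with both in WT replicates 1, 2 and 3. Rev1 knockout plates had no well with Y-linked UMIs alone and 2 with both, in replicate 3. Pcna K164R replicate 1 was mostly Y-linked and replicate 2 mostly had Xist.

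Near the altered Pcna allele, Jmjd7 (chromosome 2, 120027483 to 120032604) had a log2 fold change of -2.58 in Pcna K164R against WT and -2.24 in the double mutant against Rev1 knockout, and Tmem230 (chromosome 2, 132239492 to 132249059) 0.93 and 0.91. In Pcna K164R against WT, 14 of 241 genes within 20 Mb of Pcna had an unadjusted p under 0.05 (5.81%) against 221 of 11898 elsewhere (1.86%), an odds ratio of 3.26 (Fisher's exact p = 0.000251), a threshold picked after none passed the adjusted test. A segment of another strain carried with the allele could produce this, and predicts that these genes keep their sign in the double mutant against Rev1 knockout. All 14 did, as did 195 of 221 elsewhere (88.2%), so the test cannot tell (Fisher's exact p = 0.376). Epb4.2 (chromosome 2, 121017891 to 121036877) lies in the same stretch.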
